A study of Mus musculus with 6 samples.

How the data were processed

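RNA sequencing measured gene expression in CD4+ T cells of 6 mice. Per the labels' protocols, naive CD4+ T cells were taken from the spleen with a magnetic isolation kit, which removes other cells by bead selection. They were then stimulated for 48 h through the T cell receptor and its costimulatory receptor, with anti-CD3 bound to the plate and anti-CD28 in solution. Total RNA was extracted with a column kit. The series' design text gives 3 mice of each genotype, WT and UTX TCD. UTX TCD mice lack UTX, the histone H3K27 demethylase encoded by Kdm6a, in T cells. Which exons were deleted is not given in the sources used here. Each library comes from a separate mouse, so that the spread between libraries includes the spread between animals.

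The deposited values are raw counts of reads per gene, whole numbers with no normalization. Per the submitters' processing notes, FastQC, HISAT2 and HTSeq were used with the genome build mm10. Their versions, the annotation, the strand setting and the handling of reads that match several genes are not given in the sources used here. If the counting ignored strand, reads of overlapping genes on opposite strands cannot be told apart. Reads shared by near-identical genes may be lost or misplaced. One deposited table was used, with 4162 genes named by symbol and 1 column for each of the 6 libraries. Each column was tied to its sample through the genotype and number in the sample's title. Every row named a gene.

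The table holds part of the transcriptome. Its genes were checked for the pattern a selection would leave. Among 4118 tested genes, 20 had a log2 fold change between genotypes within 0.1 of 0, while 1019 lay between -0.4 and -0.2 and 542 between 0.3 and 0.5. The emptiest point lay at a log2 fold change of 0.07, where a window of the same width held 2 genes. A table of all expressed genes would have its densest region there. The selection therefore followed the genotype difference, and its rule is not given in the sources used here. This has 4 effects on the measurements. The total count of a column is not the depth of its library. Values in CPM, counts scaled to a fixed library total, are relative to the counts of the listed genes and run higher than in a full library. The scaling between libraries rests on genes that differ. Benjamini-Hochberg adjustment over the listed genes counts too few tests, so that adjusted p-values are smaller than they would be over all genes.

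Column totals ran from 8363326 to 10288306 counts. The gene with most counts was Ncl in each library, with 0.91% to 1.45% of the total. Replicates were compared with a chi-square statistic of their counts. Its value per degree of freedom was 7.01 to 11.6 between WT libraries and 19.7 to 86.7 between UTX TCD libraries, where sampling noise alone gives about 1, so no library was counted as a duplicate.

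Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with genotype as the only term, the default low-count filter (minimum count 10, minimum total count 15), TMM scaling and Benjamini-Hochberg adjustment over all genes tested. The filter left out 44 genes. Genes are called changed at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. Gene lists of 5 or more tested members were tested with camera of limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 30 lists tested. Camera compares a list with the other genes of the table. Listed genes had passed a selection on the genotype difference, so counts of changed list members, adjusted over the list alone or over all genes, are not independent evidence that a list changed. A list member without a row in the table gives no information. Members not analysed were, for example, 2 of 22 in the Th1 list and 58 of 72 in the oxidative phosphorylation list. A list that is not called therefore speaks only for its tested members.

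The 40 gene lists, the main tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists cover hypoxia and its regulators, metabolism, chromatin complexes, activation, helper lineages, receptors, cell cycle, stress pathways and markers of other cell types and of sex. The rule names a panel of 25 genes, the 10 genes with the largest rise and the 10 with the largest fall among changed genes whose groups did not overlap and whose average log2 CPM was at least 2, and up to 4 changed members of each list with the smallest p. From the last group the text names members whose call held whichever library was left out and counts the others. Some genes that the rule names are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

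The tests were run on simulated data first. Counts were drawn from the means and spread of the real libraries, with 200 genes changed by known folds, over 4032 genes that passed the filter. For UTX TCD against WT, 49.2% of genes changed 1.5-fold, 77.3% of those changed 2-fold and 96.9% of those changed 4-fold were recovered. Of 154 genes called, 9 were unchanged (5.8%). In a second simulation with 30 lists, the 1 list that was shifted was recovered and 0 of the others were called. Both simulations drew each gene independently, gave both genotypes the same spread and changed a small share of the genes. The deposited table differs in each of these respects, so these recovery and error rates do not carry over to it.

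Gene positions and identifiers come from GENCODE M21 on GRCm38, the assembly that mm10 names. Of the 4162 symbols, 4121 matched exactly 1 gene (99.01%), 35 matched none and 6 matched more than one. Alternatives were other scalings (RLE, library size, upper quartile), other low-count filters, DESeq2 1.42.0, limma-voom, a robust dispersion fit, the replicate number as a block, each library left out, Kdm6a, Xist and Y-linked genes left out, and for lists an estimated correlation and fry. A further 3 alternatives were chosen after seeing the data. They are a scaling that centres the gap in the fold changes on 0, a correction of each library for transcript length and GC content, and an adjustment that counts every annotated protein-coding gene as a test, 22160 tests with the other listed genes included.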

Results

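Activated splenic CD4+ T cells of 3 WT mice and 3 UTX TCD mice were compared by RNA sequencing after 48 h of anti-CD3 and anti-CD28 stimulation. The comparison addresses which genes change when T cells lack UTX, a demethylase that removes methyl groups from histone H3 lysine 27, and the series' title puts the question in terms of hypoxia sensing by T cells that cause colitis. Column totals over the 4162 listed genes were 8363326 to 10288306 counts. The first principal component of log2 CPM held 81.4% of the variance. WT libraries lay between -31.6 and -24.8 on it, and UTX TCD libraries at 18.9, 42.9 and 24.5. The listed genes had been selected on the genotype difference, so this share and the separation of the genotypes describe the table and not the transcriptome. UTX TCD replicate 2 stood apart from the other libraries of its genotype. The biological coefficient of variation was 8% among WT and 22.1% among UTX TCD libraries. CPM values are means ± SD of 3 libraries, taken over the counts of the listed genes, and log2 fold changes are UTX TCD over WT with their standard error.

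Kdm6a, the gene of UTX, was lower in UTX TCD cells. It lies on chromosome X from 18162575 to 18279936 (ENSMUSG00000037369, GRCm38). Its level was 283 ± 2.96 CPM in WT and 191 ± 14.4 CPM in UTX TCD libraries, a log2 fold change of -0.56 ± 0.09 (edgeR adjusted p = 0.0029), with no overlap between the groups. Counts over the whole gene include exons outside any deleted part. In the list of H3K27 demethylase and COMPASS complex genes, 5 of 7 tested members were higher and 1, Kdm6a itself, was lower (5 and 2 adjusted over the list alone). Of its members, Kmt2e and Kmt2c rose, by 0.55 ± 0.07 and 0.54 ± 0.07 on the log2 scale. The list as a whole was not called (median 0.38, camera adjusted p = 0.36). Among genes of PRC2, the complex that writes H3K27 methylation, 3 of 5 were higher and 1 lower (4 and 1 adjusted over the list alone, median 0.33, camera adjusted p = 0.35), with Phf1 at 0.86 ± 0.15 and Jarid2 at 0.46 ± 0.08. Without WT replicate 2 the H3K27 demethylase and COMPASS list had 2 higher members, and with the length and GC correction it had 3, at a median of 0.16. Its lower members were 2 without UTX TCD replicate 1 or 2 and with gap-centred scaling. The PRC2 list had 2 higher and 0 lower members with any 1 WT library left out and without UTX TCD replicate 3. Its lower member also did not pass with RLE or upper-quartile scaling, the replicate block or the length and GC correction, and it had 2 and 0 with every annotated gene counted as a test.

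Among 4118 tested genes, 1692 were higher and 1111 were lower in UTX TCD cells at an edgeR adjusted p under 0.05, and 530 and 273 of these differed at least 2-fold. The 10 largest rises held genes of the interferon response (Ifi208, Rsad2, Ifi44, Ifi213 and Rtp4), Mmp14, a membrane-bound matrix metalloproteinase, Myo6, an unconventional myosin, Nav1, Cybrd1, a ferric reductase, and Gm14085. Mmp14 went from 1.85 ± 1.02 to 37.1 ± 9.24 CPM (log2 fold change 4.30 ± 0.42, edgeR adjusted p = 7.6e-04), and Myo6 from 7.22 ± 2.28 to 97.3 ± 22.1 CPM (3.74 ± 0.27, 4.7e-04). The 10 largest falls were Fgr, a Src-family kinase, Pdzrn3, Thy1, Col5a3, a collagen chain, Serpinf1, Dsp, which encodes desmoplakin, Dgkk, Cavin3, Sspo and Zdbf2. Fgr went from 18 ± 0.93 to 0.72 ± 0.45 CPM (-4.65 ± 0.40, 5.3e-04). Thy1, the surface glycoprotein CD90 that marks mouse T cells, was the most abundant of them and fell from 809 ± 85.1 to 56.8 ± 18.3 CPM, 14.2-fold (-3.83 ± 0.23, 1.9e-04). It lies on chromosome 9 from 44043384 to 44048579. In 3535 genes (85.8%) the groups did not overlap, where chance gives 10%, but the listed genes had been selected on the genotype difference, so these counts describe the table and not the transcriptome. Calls split 60.4% higher with TMM, 70.6% with upper-quartile scaling (1742 higher, 725 lower) and 46.2% with a scaling that centres the gap in the fold changes on 0 (1557 higher, 1815 lower). Leaving out WT replicate 1 gave 812 higher and 402 lower genes, leaving out WT replicate 2 gave 730 and 351, and leaving out WT replicate 3 gave 1195 and 544. Without UTX TCD replicate 2 the counts were 1605 and 1458. With every annotated protein-coding gene counted as a test, 621 higher and 296 lower genes remained past the threshold. Rsad2, Ifi44 and Rtp4 rested most on UTX TCD replicate 2, without which their log2 fold changes were 2.07, 1.73 and 2.47 in place of 4.73, 4.65 and 4.01. Their calls were lost without WT replicate 1 (4.92, 4.87 and 3.95) or WT replicate 2 (4.52, 4.45 and 3.65), and for Rsad2 and Ifi44 also without WT replicate 3 (4.77 and 4.66).

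**Figure D1:**
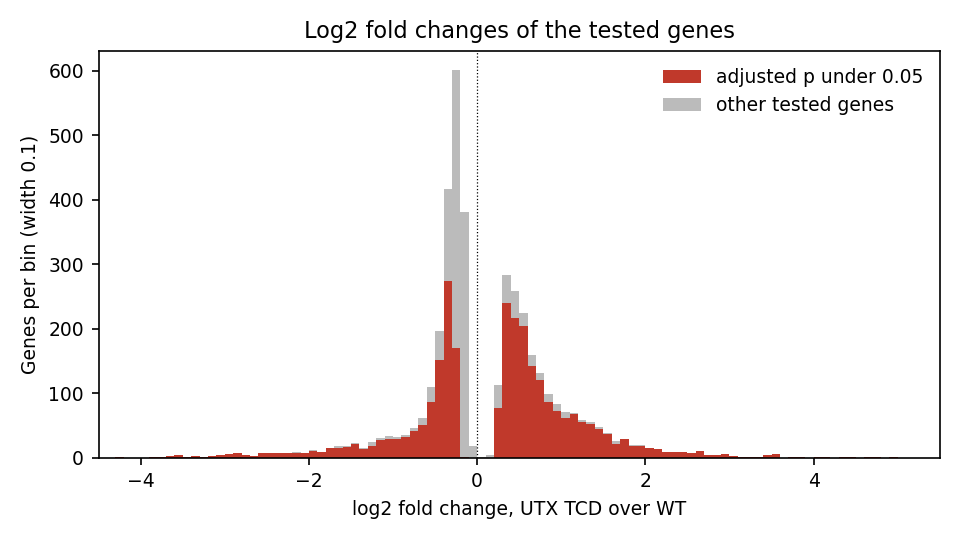
Histogram of log2 fold changes (UTX TCD over WT, x axis) in bins of 0.1, with the number of genes per bin on the y axis, for the 4118 tested genes. Red shows genes with an edgeR adjusted p under 0.05 and grey the others, and 20 genes lie within 0.1 of 0, against 1019 between -0.4 and -0.2.

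Genes of the oxygen-sensing pathway moved in both directions. Hif1a, the oxygen-regulated subunit of the hypoxia-inducible factor, rose from 1109 ± 52.9 to 1998 ± 637 CPM (log2 fold change 0.85 ± 0.20, edgeR adjusted p = 0.012), and Vegfa, a HIF target, from 59.2 ± 9.42 to 106 ± 46.1 CPM (0.85 ± 0.28, 0.032). Hif3a, a HIF family member, fell from 7.59 ± 1.06 to 1.28 ± 0.12 CPM (-2.55 ± 0.29, 0.0012), and Cited2, which competes with HIF for its coactivator, fell by 0.47 ± 0.09. Vhl, the ubiquitin ligase subunit that marks HIF for degradation, was lower at -0.34 ± 0.12 (edgeR adjusted p = 0.036), and the prolyl hydroxylase gene Egln3 did not pass at -0.46 ± 0.19 (0.056). Of 22 tested members of the HIF-1 hypoxia response list, 12 were higher, 3 lower and 7 did not pass (12 and 3 adjusted over the list alone). The higher members included Ndrg1 at 1.13 ± 0.20, Tet1 at 0.99 ± 0.15, Pnrc1 at 0.71 ± 0.09 and the mitophagy receptor gene Bnip3l at 0.61 ± 0.11. The list's median was 0.53 and it was not called against the other genes of the table (camera adjusted p = 0.26, and 0.76 with an estimated correlation). Fry, which tests the list by itself, gave an adjusted p of 0.025 and called 16 of the 30 lists tested. The listed genes had been selected on the genotype difference, so passing with fry is not independent evidence that the hypoxia list changed. Of the 60 genes fixed for the list, 38 were not analysed here. The HIF pathway regulators had 1 higher and 3 lower of 6 (1 and 4 adjusted over the list alone, median -0.40, camera adjusted p = 0.24), which became 0 and 2 without WT replicate 2, and 1 and 5 without UTX TCD replicate 1 or with gap-centred scaling. Single libraries moved several of these values. The HIF-1 list had 5 higher and 1 lower members without WT replicate 1, 5 and 1 without WT replicate 2, 8 and 1 without WT replicate 3, 13 and 5 without UTX TCD replicate 1, 11 and 5 with gap-centred scaling, and 4 and 1 with every annotated gene counted as a test. By that last count the regulators had 0 and 2. Hif1a was 0.55 without UTX TCD replicate 2, and not past the threshold without WT replicate 2 (0.81). Vegfa was 0.43 without UTX TCD replicate 2, and not past without WT replicate 1 (0.88), 2 (0.72) or 3 (0.94). Vhl was not past without WT replicate 1 (-0.35), 2 (-0.31) or 3 (-0.38), and Egln3 passed without UTX TCD replicate 1 (-0.68). Of the panel, Kdm6b, Uty, Epas1, Arnt, Egln1, Egln2, Hif1an, Slc2a1, Ldha, Pdk1, Il17a and Cd69 were not analysed here.

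**Figure D2:**
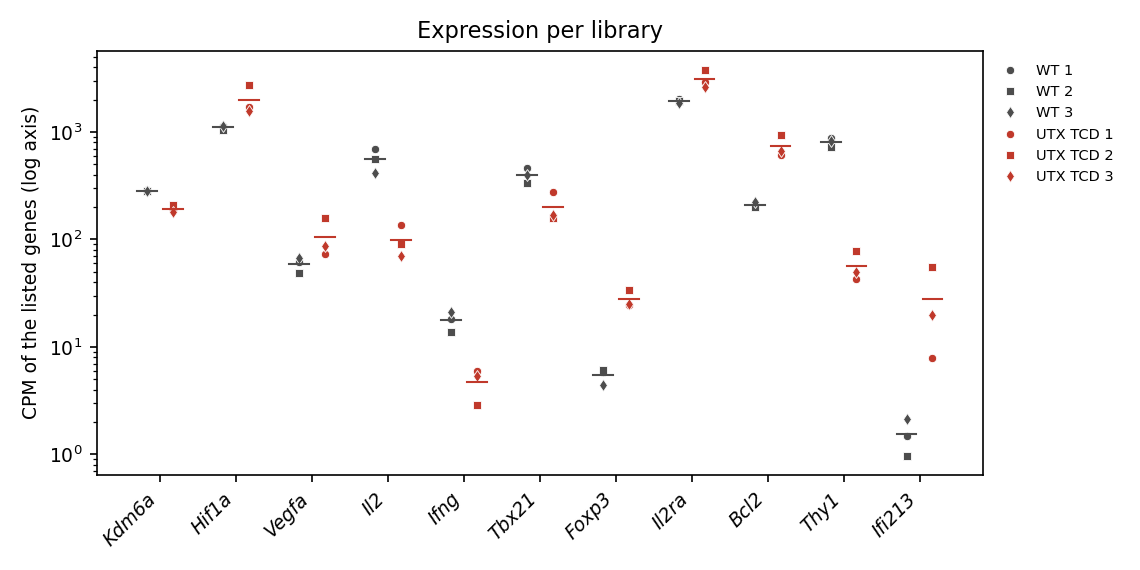
CPM of the listed genes (log y axis) of 11 genes in each library, WT in grey and UTX TCD in red, with replicates 1, 2 and 3 as circles, squares and diamonds and a bar at the mean of the 3. The genotypes do not overlap for any gene shown, and UTX TCD replicate 2 is the highest library for Hif1a, Vegfa, Foxp3, Il2ra, Bcl2 and Ifi213.

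Genes of the naive and memory state were higher in UTX TCD cells, and genes of effector function were lower. In the naive and memory T cell list, 12 of 15 tested members rose and 2 fell (13 and 2 adjusted over the list alone, median 1.47, camera adjusted p = 0.014). This list's adjusted p was 0.76 with an estimated correlation. Igfbp4 rose from 120 ± 20.3 to 741 ± 239 CPM (2.63 ± 0.24, edgeR adjusted p = 6.0e-04), Bcl2, which protects from apoptosis, from 209 ± 13.1 to 738 ± 171 CPM (1.82 ± 0.16, 5.9e-04), and Rasgrp2 from 7.23 ± 2.20 to 51.0 ± 14.6 CPM (2.82 ± 0.30, 9.7e-04). Dapl1 went the other way, from 128 ± 19.1 to 24.8 ± 4.48 CPM. In the TCR and CD28 activation response list, 6 of 30 members rose and 15 fell (6 and 16 adjusted over the list alone, median -0.55, camera adjusted p = 0.023, and 0.76 with an estimated correlation). The cytokine gene Il2 fell from 557 ± 140 to 98.8 ± 34.3 CPM (-2.50 ± 0.28, edgeR adjusted p = 0.0012), the chemokine genes Ccl3 and Ccl4 from 357 ± 57.3 to 43.3 ± 14.95 and from 196 ± 12.8 to 36.9 ± 12.5 CPM, and Tnf from 252 ± 14.7 to 97.5 ± 11.9 CPM. Il2ra, the IL-2 receptor alpha chain that activation induces, rose from 1945 ± 73.2 to 3098 ± 606 CPM (0.67 ± 0.14, 0.0076). The 6 higher members of the activation list became 3, 1 and 3 without WT replicates 1, 2 and 3, and its lower members numbered 11 to 19 with any 1 library left out. With every annotated gene counted as a test the activation list had 1 higher and 11 lower members, and the naive and memory list 11 and 1.

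The Th1 list, which shares Ifng, Tnf, Ccl3 and Ccl4 with the activation list, had 4 higher and 13 lower of 20 members (5 and 13 adjusted over the list alone, median -1.40, camera adjusted p = 0.026, and 0.76 with an estimated correlation). Ifng fell from 17.9 ± 3.75 to 4.77 ± 1.68 CPM (-1.91 ± 0.33, edgeR adjusted p = 0.0043), Tbx21, the Th1 transcription factor T-bet, from 397 ± 62.5 to 201 ± 66.3 CPM (-0.98 ± 0.23, 0.011), Il12rb1 from 668 ± 10.01 to 245 ± 50.7 CPM and Fasl from 54.2 ± 2.00 to 18 ± 1.04 CPM. In the secreted effector and cytotoxic list 5 of 23 rose and 12 fell (5 and 12 adjusted over the list alone, median -1.17, camera adjusted p = 0.035, and 0.76 with an estimated correlation). It shares Ifng, Tnf, Ccl3 and Ccl4 with both the activation and the Th1 list. It also shares Fasl, Gzmb and Nkg7 with the Th1 list and Il2 and Xcl1 with the activation list, so its call is not separate evidence. The call of this list was lost with no low-count filter (camera adjusted p = 0.057), without UTX TCD replicate 3 (0.086) and with gap-centred scaling (0.084), and that of the Th1 list with gap-centred scaling (0.056). Higher members were fewer without WT replicate 1 (1 in the Th1 and 3 in the effector list), WT replicate 2 (1 and 1) and UTX TCD replicate 2 (1 and 3), and without WT replicate 3 in the Th1 list (2), while lower members numbered 10 to 11 and 11 to 14 with any 1 library left out. The Th1 list had 2 higher members with limma-voom or gap-centred scaling, and both lists had 1 higher and 9 lower with every annotated gene counted as a test.

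**Figure D3:**
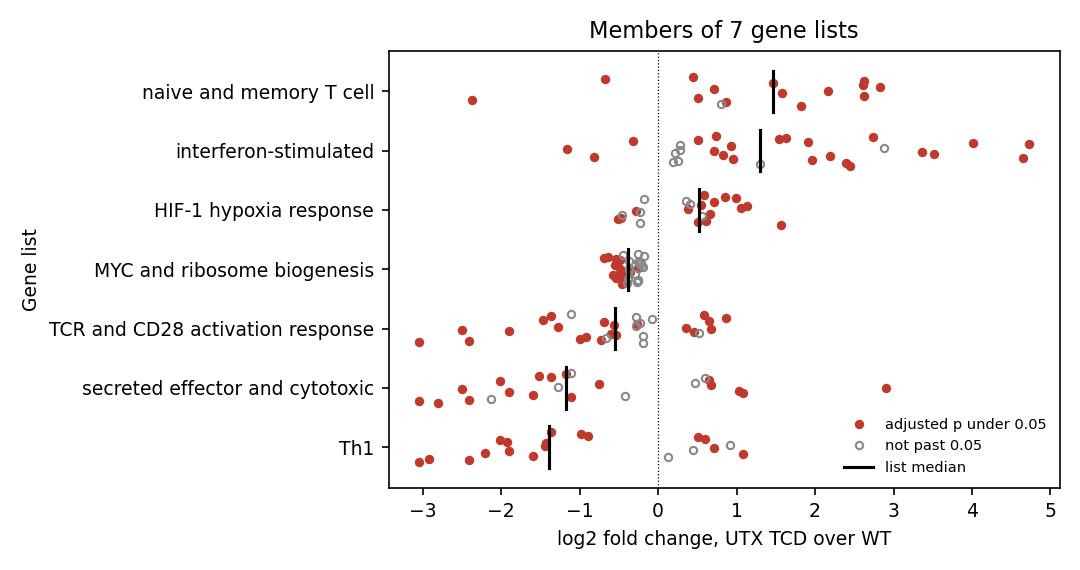
Log2 fold changes (UTX TCD over WT, x axis) of the tested members of 7 gene lists (y axis), filled where the edgeR adjusted p was under 0.05, with a bar at each list's median. The medians run from -1.40 for the Th1 list to 1.47 for the naive and memory T cell list.

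Lists of the other helper lineages were not called. In the regulatory T cell list 7 of 11 rose and 3 fell (7 and 4 adjusted over the list alone, median 0.66, camera adjusted p = 0.36). Foxp3, the lineage transcription factor of regulatory T cells, rose from 5.45 ± 0.89 to 27.9 ± 5.33 CPM (2.35 ± 0.23, edgeR adjusted p = 7.6e-04), Gpr83 rose by 1.71 ± 0.14 and Nrp1 fell by 1.47 ± 0.15. The Th17 list had 3 higher and 4 lower of 10 (3 and 4 adjusted over the list alone, median -0.69, camera adjusted p = 0.55). Its members Il6st and Ahr rose, by 0.83 ± 0.09 and 1.18 ± 0.22. The T follicular helper list had 2 higher and 5 lower of 10 (2 and 5 adjusted over the list alone, median -0.42, camera adjusted p = 0.35), with Bcl6 at -0.78 ± 0.15, Pdcd1 at -1.46 ± 0.27 and Cd40lg at -0.88 ± 0.14. The Th2 list had 4 higher and 1 lower of 7 (4 and 1 adjusted over the list alone, median 0.35, camera adjusted p = 0.91). Gata3 was higher at 1.10 ± 0.39 (edgeR adjusted p = 0.038) with overlapping groups, and did not pass without WT replicate 2 (0.96), WT replicate 3 (0.86), UTX TCD replicate 1 (0.91) or UTX TCD replicate 2 (0.95). These counts moved with single libraries. Lower members of the regulatory T cell list became 1 without WT replicate 2. The Th17 list had 2 higher and 2 lower members without WT replicate 1 or 2, and 3 and 2 without UTX TCD replicate 3. The T follicular helper list had 0 and 3 without WT replicate 2. The Th2 list had 1 and 1 without WT replicate 2, 2 and 1 without WT replicate 3, 3 and 2 without UTX TCD replicate 2, 4 and 2 without UTX TCD replicate 3, and 4 and 3 with gap-centred scaling. With every annotated gene counted as a test the regulatory T cell, Th17, T follicular helper and Th2 lists had 6 and 1, 2 and 1, 0 and 3, and 0 and 1. Medians moved too, for Th17 to -1.12 without UTX TCD replicate 2, for T follicular helper to -0.67 without UTX TCD replicate 3 and for Th2 to 0.20 with the length and GC correction.

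Surface receptors also went both ways. The costimulatory and inhibitory receptor list had 8 higher and 11 lower of 21 (8 and 11 adjusted over the list alone, median -0.42, camera adjusted p = 0.36), with Cd28 at 0.83 ± 0.11, Cd27 at 0.87 ± 0.13 and Cd86 at -3.52 ± 0.39. The homing and adhesion list had 7 higher and 10 lower of 21 (8 and 10 adjusted over the list alone, median -0.22, camera adjusted p = 0.51). The chemokine receptor gene Cxcr4 rose by 2.18 ± 0.27 and the integrin gene Itgal fell by 0.85 ± 0.11. The T cell receptor complex list had 3 higher and 3 lower of 8 (3 and 3 adjusted over the list alone, median -0.14, camera adjusted p = 0.65). Apart from Thy1, its members Themis and Lat were at 0.69 ± 0.13 and -0.44 ± 0.08. Without WT replicates 1, 2 and 3 the costimulatory and inhibitory list had 4 higher and 8 lower, 3 and 6, and 5 and 7 members, and with gap-centred scaling it had 4 and 12. The homing and adhesion list had 4 and 5 without WT replicate 1 or 2. With every annotated gene counted as a test these lists had 3 and 6, and 4 and 3. The homing median was -0.34 without UTX TCD replicate 1, -0.14 without UTX TCD replicate 3 and -0.15 with upper-quartile scaling. That of the T cell receptor complex was -0.07 with upper-quartile and -0.22 with gap-centred scaling and -0.09 with the length and GC correction.

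Interferon-stimulated genes were higher in UTX TCD cells, most of all in replicate 2. Of 29 tested members, 19 rose and 3 fell (21 and 3 adjusted over the list alone, median 1.30, camera adjusted p = 0.026). The adjusted p was 0.76 with an estimated correlation and 0.14 with fry. UTX TCD replicate 2 held the highest value of 24 of the 29 genes. Without that library 19 genes were higher and 3 lower, the median was 0.63, and the camera adjusted p was 0.0053. The members called higher were 7, 5 and 9 without WT replicates 1, 2 and 3, with the list still called each time (camera adjusted p = 0.018, 0.032 and 0.030). With limma-voom 11 were higher and 3 lower (median 1.00), with the length and GC correction 21 and 1, and with every annotated gene counted as a test 3 and 0. Slfn1 rose from 108 ± 17.0 to 409 ± 234 CPM (1.92 ± 0.36, edgeR adjusted p = 0.0057), Ifit2 by 0.82 ± 0.15 and Ifi35 by 0.96 ± 0.21. Chosen after its values were seen, Irf7 had 5.86 to 7.95 CPM in WT libraries and 18.4, 179 and 20.5 CPM in UTX TCD replicates 1, 2 and 3.

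Genes of ribosome biogenesis were lower. In the list of MYC targets and ribosome biogenesis 0 of 35 tested members rose and 17 fell (0 and 5 adjusted over the list alone, median -0.38, camera adjusted p = 8.3e-04), while the adjusted p was 0.76 with an estimated correlation and 0.096 with fry. Without UTX TCD replicate 2, 0 rose and 26 fell, at a median of -0.23. The members that fell were 3, 3 and 5 without WT replicates 1, 2 and 3, 31 without UTX TCD replicate 1, 10 with upper-quartile, 11 with RLE and 29 with gap-centred scaling, and 2 with every annotated gene counted as a test. Odc1, the first enzyme of polyamine synthesis, fell from 1251 ± 44.9 to 855 ± 87.3 CPM (-0.55 ± 0.10, edgeR adjusted p = 0.0047), Rrp9 by 0.69 ± 0.14 and the chaperonin gene Hspe1 by 0.53 ± 0.12.

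Metabolic lists were not called, and the values cover only the members that remained in the table. Members not analysed here were 16 of 26 for glycolysis, 58 of 72 for oxidative phosphorylation and 18 of 25 for the tricarboxylic acid cycle. For the amino acid, cholesterol and mTORC1 lists they were 18 of 31, 20 of 32 and 20 of 27. Glycolysis had 3 higher and 3 lower of 10 (3 and 3 adjusted over the list alone), with a negative median of -0.23, a positive mean of 0.18 and a camera adjusted p of 0.68 in the lower direction, and its member Pfkm rose by 0.65 ± 0.14. Nuclear genes of oxidative phosphorylation had 1 higher, Ndufv3 at 0.59 ± 0.12, and 2 lower of 14 (1 and 2 adjusted over the list alone, median -0.21, camera adjusted p = 0.15). The tricarboxylic acid cycle had 2 higher and 2 lower of 7 (0 and 0 adjusted over the list alone, median -0.24, 0.57), amino acid transport and one-carbon metabolism 2 and 2 of 13 (0 and 0, median -0.18, 0.53), and cholesterol and fatty acid synthesis 3 and 1 of 12 (3 and 0, median -0.15 with a mean of 0.09, 0.76). For mTORC1 and autophagy 5 of 7 rose and 0 fell (5 and 0, median 0.33, 0.36), among them Sesn1 at 0.75 ± 0.15. Each of these counts moved with single libraries or with the scaling. Without WT replicate 1 or 2 glycolysis had 1 higher and 0 lower members, and oxidative phosphorylation 1 and 0. Without WT replicate 3 they had 2 and 1, and 1 and 1. Lower members of oxidative phosphorylation were 4 without UTX TCD replicate 2, 7 without UTX TCD replicate 3 and 12 with gap-centred scaling. With any 1 WT library left out the tricarboxylic acid cycle and amino acid lists had 0 and 0. Without UTX TCD replicates 1, 2 and 3 the tricarboxylic acid cycle had 2 and 4, 2 and 5, and 1 and 1, and the amino acid list 4 and 4, 4 and 7, and 4 and 0. With gap-centred scaling they had 1 and 5, and 2 and 6, and with RLE or upper-quartile scaling 2 and 0, and 4 and 0. Cholesterol and fatty acid synthesis had 0 and 0 without WT replicate 1, 1 and 0 without WT replicate 2 or 3, 4 and 2, 3 and 5, and 3 and 0 without UTX TCD replicates 1, 2 and 3, and 3 and 3 with gap-centred scaling. For mTORC1 and autophagy the counts were 1 and 0 without WT replicate 1 or 2, 2 and 0 without WT replicate 3, 5 and 1 without UTX TCD replicate 1 or 2, 3 and 0 without UTX TCD replicate 3, and 4 and 2 with gap-centred scaling. The tricarboxylic acid cycle had 2 and 0 with DESeq2, 1 and 0 with the replicate block, and 2 and 1 with library-size scaling or the length and GC correction. The amino acid list had 4 and 0 with DESeq2, 3 and 1 with library-size scaling and 1 and 3 with limma-voom. The lower member of cholesterol and fatty acid synthesis did not pass with RLE, library-size or upper-quartile scaling, DESeq2 or the replicate block. The length and GC correction gave mTORC1 and autophagy 4 and 1. Counting every annotated gene as a test left 1 and 0 in the glycolysis, oxidative phosphorylation and mTORC1 lists and 0 and 0 in the others. The glycolysis median was -0.138 without UTX TCD replicate 3 and -0.141 with the length and GC correction. Medians of oxidative phosphorylation and the tricarboxylic acid cycle were -0.136 and -0.144 without UTX TCD replicate 2 and -0.107 and -0.115 with the length and GC correction, and with upper-quartile scaling that of oxidative phosphorylation was -0.134. The amino acid median was -0.101 with upper-quartile scaling, and the cholesterol median -0.065 with it and -0.059 without UTX TCD replicate 3.

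Cell cycle and stress lists were not called either. Members not analysed here were 36 of 46 for G1/S, 42 of 53 for G2/M and 17 of 32 for p53 and apoptosis. For the unfolded protein response, heat shock and NRF2 lists they were 12 of 24, 11 of 22 and 18 of 28. The G1/S list had 3 higher and 1 lower of 10 (3 and 1 adjusted over the list alone, median -0.14, camera adjusted p = 0.68), with Ccne1, which encodes cyclin E1, at -0.51 ± 0.10. The G2/M list had 5 higher and 2 lower of 11 (5 and 2, median -0.09 with a mean of 0.04 and a test in the higher direction, 0.89), with Nusap1 at 0.62 ± 0.09. In the p53 and apoptosis list 8 of 15 rose and 3 fell (8 and 3, median 0.37, 0.55), with Trp53inp1 at 1.30 ± 0.25. The unfolded protein response had 2 higher and 5 lower of 12 (2 and 4, median -0.27, 0.24), with Xbp1 at 0.59 ± 0.11. Heat shock and immediate early genes had 3 and 4 of 11 (3 and 4, median -0.30, 0.41), with Ier2 at -0.47 ± 0.09. Reactive oxygen and NRF2 genes had 2 and 4 of 10 (2 and 2, median -0.25, 0.36). These counts moved likewise. The G1/S list had 0 higher and 1 lower with any 1 WT library left out, 3 and 2, 3 and 3, and 1 and 1 without UTX TCD replicates 1, 2 and 3, and 3 and 4 with gap-centred scaling. The G2/M list had 1 and 0 without WT replicate 1 or 2, 3 and 0 without WT replicate 3, 5 and 4 without UTX TCD replicate 2, 3 and 2 without UTX TCD replicate 3, and 4 and 5 with gap-centred scaling. The p53 list had 5 and 1, 4 and 0, and 7 and 1 without WT replicates 1, 2 and 3. The unfolded protein response had 1 and 0 without WT replicate 1 or 2, 1 and 3 without WT replicate 3, 2 and 10 without UTX TCD replicate 1, 2 and 3 without UTX TCD replicate 3, and 2 and 9 with gap-centred scaling. Heat shock and immediate early genes had 0 and 2, 1 and 2, and 2 and 2 without WT replicates 1, 2 and 3, and 3 and 7 without UTX TCD replicate 2. Reactive oxygen and NRF2 genes had 0 and 1, 0 and 0, and 1 and 0 without WT replicates 1, 2 and 3, 2 and 8 with gap-centred scaling, and 2 and 1 with RLE or upper-quartile scaling or the length and GC correction. The G2/M list had 5 and 1 with RLE, library-size or upper-quartile scaling or DESeq2, and 4 and 1 with the length and GC correction. The p53 list had 8 and 1 with upper-quartile scaling and 8 and 5 with the replicate block. The unfolded protein response had 2 and 3 with upper-quartile scaling and 1 and 5 with limma-voom, and reactive oxygen and NRF2 genes 2 and 2 with library-size scaling or DESeq2. Counting every annotated gene as a test left 0 and 1, 1 and 0, 4 and 0, 1 and 0, 0 and 1, and 0 and 0 in the 6 lists in the order given. The G1/S median was -0.065 without UTX TCD replicate 2, -0.064 with upper-quartile and -0.212 with gap-centred scaling. That of G2/M was -0.036 without UTX TCD replicate 2, -0.014 with upper-quartile, -0.047 with RLE and -0.163 with gap-centred scaling, -0.049 with DESeq2 and -0.048 with the length and GC correction. With that correction the medians of the unfolded protein response and the NRF2 list were -0.174 and -0.125.

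Markers of other cell types were few in the table. Of the CD8 T cell markers 3 rose and 2 fell among 7 (3 and 2 adjusted over the list alone, median 0.60, camera adjusted p = 0.68). Cd8b1, the CD8 beta chain, rose from 13 ± 1.48 to 42.8 ± 12.5 CPM (1.72 ± 0.24, edgeR adjusted p = 0.0023), while Nkg7 and Crtam fell, by 2.02 ± 0.21 and 2.64 ± 0.42. Without WT replicate 1 or 2, 1 of the CD8 T cell markers rose and 2 fell, as with every annotated gene counted as a test. Lists with fewer than 5 tested members were not tested as lists. Of 4 B cell markers 0 rose and 2 fell, and neither fall passed with any 1 WT library left out. Of 4 NK and innate-like markers, Tcrg-C1 rose from 0.36 ± 0.19 to 2.26 ± 0.18 CPM and 1 fell. The dendritic cell marker Ccl22 fell by 1.08 ± 0.22 and the endothelial marker Pecam1 rose by 1.29 ± 0.21. The 1 macrophage and the 1 erythroid marker did not pass, and neutrophil markers, mitochondrially encoded genes and Y-linked genes had 0 members among the genes analysed. Xist, expressed from the inactive X chromosome, was at 2793 to 2910 CPM in WT and 3896 to 4350 CPM in UTX TCD libraries (0.55 ± 0.08, edgeR adjusted p = 0.0029). Of the 5 X-linked genes in the list of dosage-variable genes, Xist rose, Kdm6a fell and 3 did not pass.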

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

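The gap-centred scaling, the length and GC correction and the adjustment over every annotated gene were chosen after seeing the data. The other alternatives were fixed before. Kdm6a was lower and past the threshold under all 18 alternatives, with log2 fold changes of -0.64 to -0.48. The other edgeR scalings moved all genes nearly alike and by less than any changed gene had changed, so they could reverse none. Under the length and GC correction 6 changed genes reversed, among the named genes Kmt2d at -0.0071 with 0.38 before. Lower genes numbered 725 with upper-quartile scaling and 1815 with gap-centred scaling. With every annotated protein-coding gene counted as a test, 621 genes were higher and 296 lower, fewer because more tests were counted. DESeq2 called 1781 higher and 928 lower, and limma-voom 1654 and 1196. With 1 library left out, higher genes ranged from 730 to 1824 and lower genes from 351 to 1458, and 994 of the 2803 changed genes passed whichever library was left out. Of 140 named genes past the threshold, 87 passed whichever library was left out. The HIF-1 hypoxia response list was past the threshold only with fry (median 0.5262, adjusted p 0.025). It had camera adjusted p-values of 0.19 to 0.35 under 17 alternatives. With an estimated correlation camera called 0 lists, where 1 had an unadjusted p under 0.05 against 7 with the preset correlation. The estimates were -0.004 in the secreted effector, 0.02 in the Th1, 0.09 in the activation and 0.31 in the naive and memory list. They were 0.70 in the interferon and 0.88 in the ribosome biogenesis list. In the secreted effector list the estimate lay below the preset 0.01, so correlated members do not account for the loss of its call. Fry, which does not compare a list with other genes, called 16, among them 4 of the 6 lists that camera called. The listed genes had been selected on the genotype difference, so calls by fry are not independent evidence that a list changed. Directions of lists far from the threshold reversed: the Th2 list without WT replicate 2 (median 0.2894), without WT replicate 3 (0.3512) and with fry (0.3511), where the test turned and the median did not, and without UTX TCD replicate 3 the G2/M list (-0.1178) and the cholesterol and fatty acid list (-0.0589). With 1 library left out, these medians ranged from 0.2894 to 0.4307 for Th2, from -0.1252 to -0.0365 for G2/M and from -0.1873 to -0.0589 for cholesterol and fatty acids. For these reversals, for Kmt2d and for the smaller counts without a WT library the cause was not tested. With any 1 library left out, 0 of the changed genes reversed sign. The groups did not overlap in 85.8% of tested genes, where leaving out 1 library has little room to reverse a sign. The edgeR fit gives a gene the same dispersion in both genotypes. The biological coefficient of variation was 8% among WT and 22.1% among UTX TCD libraries. Kdm6a was at -0.56, -0.57 and -0.57 without WT replicates 1, 2 and 3. Its standard error was 0.11 each time, against 0.09 with all libraries. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.28, -0.28 and 0.18, and 3 of the 6 libraries correlated best with their own number. With the replicate block 1607 genes were higher and 1026 lower. A covariate for sex could not be fitted, since Xist was high in all 6 libraries and Y-linked genes had no row. The filter at 1 CPM in 3 libraries kept 4130 genes, more than the main filter. Low counts kept 44 listed genes out of the main tests.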

Other observations

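All tests in this part were chosen after the results were seen, except the counts over other splits of the libraries, and so were the genes named here that the rule for named genes does not name. Gene families, taken by the letters with which their symbols begin, were compared with the other tested genes in 83 families of at least 6 members (one-sided Fisher's exact tests for higher and for lower genes, Benjamini-Hochberg over both). Of 78 zinc finger genes named Zfp, 55 were higher in UTX TCD cells and 5 lower (median 0.46, adjusted p = 1.8e-05). Across 5 other scalings or tools and the length and GC correction, 51 to 56 were higher and 3 to 15 lower, with 15 lower under gap-centred scaling and 9 with the length and GC correction. Without WT replicates 1, 2 and 3 the family did not pass, with 21, 23 and 34 higher (adjusted p = 1, 0.18 and 0.14), and it passed without each UTX TCD library, with 49 to 55 higher and 3 to 12 lower. Of 29 genes of the large subunit of the mitochondrial ribosome (Mrpl), 0 were higher and 17 lower (median -0.28, adjusted p = 0.023), Mrpl17 by 0.50 ± 0.11 and Mrpl1 by 0.39 ± 0.08. Across the same 5 other scalings or tools and the length and GC correction, 9 to 29 of them were called lower. Without WT replicates 1, 2 and 3, 3, 4 and 8 were lower, and without UTX TCD replicates 1, 2 and 3, 17, 21 and 20, and the family passed only without UTX TCD replicate 2 (adjusted p = 0.0039) or 3 (1.7e-05). Of 12 genes named Ifi, 11 were higher and 0 lower (median 2.49, adjusted p = 0.023), but 7 of the 12, with 6 of the higher ones, lie in the Ifi200 gene cluster on chromosome 1. The other 5 were all higher (median 0.96). Without UTX TCD replicate 2 the family did not pass, with 10 higher and 1 lower (median 1.37, adjusted p = 0.072), and 4 of the 5 outside the cluster were higher (median 0.66). With each other library left out it passed only without WT replicate 1 (8 higher, adjusted p = 0.027), and 6 were higher without WT replicate 2. The 7 listed genes with symbols beginning in Gimap, which name GTPases of lymphocytes and the opposite-strand transcript Gimap1os, were all higher (median 0.94), Gimap7 most at 2.08 ± 0.34, but the family did not pass (adjusted p = 0.081). With 1 library left out 6 or 7 were higher, and it passed without WT replicate 1 (0.027) or 2 (0.015). Of 13 major histocompatibility genes named H2, 10 were higher and 0 lower (adjusted p = 0.21), with 6 higher under gap-centred scaling and 12 with DESeq2. Without WT replicates 1, 2 and 3, 1, 1 and 7 were higher, and without UTX TCD replicates 1, 2 and 3, 11, 5 and 6. Of 6 chemokine genes named Ccl, 0 were higher and 5 lower (adjusted p = 0.18), and the family passed without WT replicate 1 (0.0074), 2 (0.0041) or 3 (0.034). Some members of the Zfp, Ifi and H2 families may share sequence with similar genes, which was not checked here. How the counting split such reads is not given in the sources used here. Because the table was selected on the genotype difference, these tests compare families among genes that differ. They also count each gene as independent, while genes of a family can change together. The estimated inter-gene correlation was 0.70 in the interferon list and 0.88 in the ribosome biogenesis list. The adjusted p-values of families can therefore be too small.

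The genotype split of the 6 libraries called 2803 genes, and the other 9 of the 10 splits called at most 0. The genotype split was the only 1 to reach its count, and 10 splits are too few for a share under 0.05. The listed genes had been selected on this split. For gene lists the genotype split called 6 and the highest other split also called 6, so that 2 of the 10 splits reached that number. That other split set WT replicates 1 and 3 and UTX TCD replicate 2 against the rest.

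The first pattern is the rise of naive genes with the fall of TCR response, Th1 and effector genes. A larger share of unactivated cells in the UTX TCD cultures would dilute each activation gene. However, 4 members of the activation list rose under the main and each other scaling. They were Il2ra (0.67 ± 0.14), Nr4a3 (0.65 ± 0.19), Icos (0.46 ± 0.11) and Spry2 (0.87 ± 0.28). Of these, Il2ra kept its call whichever library was left out. Dilution alone would not raise these 4 genes. The rule for this check required Il2ra and was written after its value was seen, so its outcome is not independent support. Il2ra is also on the regulatory T cell list. A bias by gene length and GC content is argued against, since after its correction the median of each of the 4 lists kept at least 93% of its size. Dilution as a cause of the rest of the pattern stays open, as does the loss of UTX itself. That loss is the difference that the design names, and it was not tested beyond the comparison of genotypes.

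The second pattern is the rise of interferon-stimulated genes. An interferon response in UTX TCD replicate 2 alone would leave no rise without that library. A median of 0.634 remained without it, against 1.30 with it, so the rise of the tested members was not confined to replicate 2. However, the listed genes had been selected on the genotype difference, which can leave out genes raised in replicate 2 alone. With 20 of the 49 fixed members not analysed here, the remaining median cannot decide this explanation. A chromosome 1 segment of another mouse strain, carried along at the Ifi200 gene cluster, could raise genes there, but the list could not test it, since 0 of its members lie in the cluster and 28 of 29 lie off chromosome 1, with 18 of these higher. For the cluster itself (chromosome 1, from 173350879 to 173942672) it cannot be told apart from an effect of the genotype. There 7 of 9 listed genes were above the WT libraries in both UTX TCD replicates 1 and 3. Without replicate 2, Ifi209 was at 2.84 and Ifi213 at 3.16. Aim2 was lower at -1.21 ± 0.18, and at -1.42 without replicate 2. Ifi211 did not pass at -0.50 but was lower without replicate 2, at -1.08. The cluster's genes resemble each other, and every UTX TCD library shares the genotype.

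The third pattern is the 14.2-fold fall of Thy1. Fewer T cells in the UTX TCD libraries would lower the other genes of the T cell receptor complex alike, but the median of the other 6 listed, without Cd8b1, was -0.144, and Themis rose by 0.69 ± 0.13. A strain segment or inserted sequence near Thy1 on chromosome 9 cannot be told apart from an effect of the genotype. Counts per gene do not show sequence, and each UTX TCD library shares the genotype. The 11 listed genes within 2 Mb of Thy1 had a median absolute log2 fold change of 0.397, against 0.448 over all tested genes. They moved in both directions, with the largest fall in Mpzl2 at -2.80 and the largest rise in Tmem136 at 2.29. An effect of UTX loss on Thy1 itself was not tested beyond the comparison of genotypes.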
